A study of Rattus norvegicus with 10 samples.

How the data were processed

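The series held 10 expression arrays of rat liver RNA in 5 groups of 2 arrays: sham rats, labelled 0 h, and rats 1, 4, 8 and 24 h after a burn injury. The deposited values were intensity values on a linear scale, 1 per probe set and array, for 8799 probe sets, and ran from 0.1 to 97822.9. The authors had scaled each array to a common trimmed mean, since the mean after removal of 2% of the values at each end lay between 500.9 and 501 on every array. The software behind the deposited values is not given in the sources used here. The labels do not say whether the 2 arrays of a group came from separate animals or from pooled tissue, so every p-value here measures only the spread between these arrays, which may be technical.

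The arrays were used as deposited, because their trimmed means lay within 10% of each other. Every value under 36.4, the median of the arrays' 25th percentiles, was raised to 36.4, and the values were then put on the log2 scale. A fold against a group with both arrays at that floor is a lower bound and is written with "at least". Folds are ratios of geometric means after this step, so they differ from ratios of the mean intensities printed. With 1 of 2 arrays of a group under the floor they depend on it: Ces2e and Abcc3 at 1 h, Gtf2ird1, Slc16a6, Zfp354a, LOC102547700 and Pla2g1b at 4 h, Lcn2, Ces2e, Gpam and Jak2 at 8 h, and LOC102547700, Ppil3, Lcn2 and Hba-a3 at 24 h. Probe sets above the median of their array on at least 2 of the 10 arrays were tested, which left 5285. Probe sets were named from the probe table of the array: 7018 had 1 gene symbol, 308 had several and 1473 were not listed and stayed unnamed. The probe sets with 1 symbol covered 4737 genes, of which 3143 were tested.

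The 5 groups were fitted in 1 model with limma 3.58.1 in R 4.3.3, with no covariate, which left 5 residual degrees of freedom. Each burn group was compared with sham by limma's moderated statistic (two-sided), and a probe set was called when its Benjamini-Hochberg adjusted p over the 5285 probe sets was under 0.05. The same model gave a moderated F test over the 4 burn times and a contrast of the mean of the 4 burn groups with sham. A further fit of the 8 burn arrays compared the 8 h and 24 h arrays with the 1 h and 4 h arrays. Changes are given as log2 changes with the standard error (SE) of the model, and every gene named as risen or fallen against sham had both burn arrays on that side of both sham arrays. The number of arrays limits the precision of every value.

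A set of 37 gene lists, 29 for processes and 8 for cell types, was tested with camera at a preset correlation of 0.01. A gene with several probe sets was represented by the one with the highest mean. The neutrophil marker list had 3 tested genes, fewer than the 4 required, and was not tested. The adjustment covered 36 lists at 4 times, 144 tests. Beside it stand camera with a correlation estimated from the arrays and fry, which asks whether the genes of a list move on balance in 1 direction and does not compare them with other genes. With an estimated correlation, the pancreas, muscle and adipose marker list at 1 h and at 4 h were the only list calls that held. In every called list the median, mean and test had the same sign, and among lists not called they differed for 3 lists at 1 h, 9 at 4 h, 9 at 8 h and 3 at 24 h.

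The groups, the comparisons, the floor, the filter, the lists, most alternative settings and the rule for named genes were fixed before the data were examined. The rule took, at each time, the 10 genes with the largest increase and the 10 with the largest decrease among those called with both burn arrays beyond both sham arrays. It also took the 4 members of each list with the smallest p of the F test and, for the comparison of late and early burn arrays, the 5 genes with the largest change in each direction. Only 4 genes rose in the last comparison. The alternatives were quantile normalization, a floor at the 10th or 50th percentile, no filter, an intensity trend with robust variance, the replicate number as a block, only the groups compared, plain probe set designs alone, and each array left out in turn. A group left with 1 array was assumed to vary like the others. An analysis without the pancreatic enzyme genes and an analysis without the 1 h arrays were added after seeing the data.

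The arrays of a group correlated with each other at 0.9483 to 0.9552, and no array correlated with an array of another group above 0.9411. Between 8 and 24 probe sets had identical values on the 2 arrays of a group, so no array was a copy of another. Between 9.63% and 12.19% of the tested probe sets differed over 2-fold between the arrays of a group. On simulated data with 2-fold and 4-fold changes set into 100 probe sets each, the model at 4 h called 33% and 69% of them with 2 false calls. The F test called 13% and 62% with 0 false calls, and the comparison of late and early arrays called 59% and 85% with 6 false calls. In the same test the only shifted list was called and 0 of the other lists were.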

Results

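Gene expression was measured in rat liver at 0 h in sham rats and at 1, 4, 8 and 24 h after a burn injury, with 2 arrays per group and 10 arrays in all. Median intensity ran from 100.1 on the first 8 h array to 131.1 on the second 1 h array, and 70.3% to 76.85% of the probe sets of an array lay above the floor of 36.4. The labels give no aim beyond the times, which imply a comparison of each burn time with sham.

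At 1 h after the burn, genes for the enzymes of pancreatic juice had the largest increases in the liver samples. Prss2, a trypsinogen, rose 13.4-fold, from a mean intensity of 70.4 to 916 (log2 change 3.75, SE 0.27, n = 2 and 2, adjusted p = 0.00169). Ctrb1 (chymotrypsinogen) rose 9.43-fold, Pnlip (pancreatic lipase) 9.4-fold on D88534_s_at and 5.44-fold on M58369_at, Cpb1 7.03-fold and Cpa1 5.34-fold (carboxypeptidases), Cel (carboxyl ester lipase) 5.28-fold, the trypsin gene Prss3b 6.68-fold and Prss3bl1 at least 5.09-fold. Rnase1, a secreted ribonuclease, rose 10.6-fold, and Reg1a, known from the exocrine pancreas, rose at least 10.5-fold. Of the 19 tested genes in the pancreas, muscle and adipose marker list, 9 rose, 0 fell and 10 did not pass, and 12 rose when adjusted over the list alone (camera adjusted p = 2.78e-13, and 0.0482 with an estimated correlation). All 9 were pancreatic enzyme genes. The insulin genes Ins1 and Ins2 of the same list had log2 changes of 0.24 and 0.02 with adjusted p of 0.702 and 0.991.

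The largest decrease at 1 h was that of the carboxylesterase gene Ces2e, 28.4-fold (SE 0.42 on the log2 scale, adjusted p = 0.00268), and the cytochrome P450 gene Cyp2b3 was at least 9.82-fold lower. Ugt2b1, a glucuronosyltransferase gene, was 3.32-fold lower (SE 0.16 on the log2 scale), and Prim1, a DNA primase gene, was at least 4.0-fold lower. Nr0b2, the nuclear receptor SHP, was 6.0-fold lower, the serine synthesis gene Psat1 at least 5.08-fold, the proteasome subunit gene Psmd1 4.83-fold, the transporter genes Slc6a9 and Abcc3 3.05-fold and 4.56-fold, and Supt5h 3.46-fold. Some of these calls ended with 1 array left out: Nr0b2 without either sham array (adjusted p up to 0.0715), and Prss3b, Psmd1 and Slc6a9 without any sham or 1 h array (up to 0.107, 0.118 and 0.14). Cpa1 and Psat1 did not pass without sham array 1 or either 1 h array (up to 0.0861 for both), nor Cel without sham array 2 or either 1 h array (up to 0.116). Abcc3 passed without 1 h array 1 (log2 change -2.81, and -1.57 without 1 h array 2) and did not without any other array (up to 0.162), and Supt5h passed without either 8 h array and did not without any other (up to 0.218). With the floor at the 50th percentile Prss3bl1, Psat1, Psmd1 and Prim1 did not pass (adjusted p = 0.128, 0.149, 0.0581 and 0.361). Prss3bl1 did not pass with an intensity trend and robust variance either (0.0818). Abcc3 and Supt5h did not pass after quantile normalization (0.0514 and 0.0823) or with the floor at the 10th percentile (0.131 and 0.0577). The same held with no filter (0.0951 each) and without the pancreatic enzyme genes (0.0526 and 0.0566), and for Supt5h with plain designs (0.0549).

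Conjugation enzymes fell as a list at 1 h (median log2 change -0.143, adjusted p = 0.00263, and 0.135 with an estimated correlation): 0 of 28 genes rose, 3 fell and 25 did not pass, and 3 fell when adjusted over the list alone. The median was -0.226 without sham array 1 and -0.249 without 1 h array 2, and the list was not called with plain probe set designs alone (adjusted p = 0.152). Ugt2b1 was among the 3, as was the glutathione transferase gene Gsta3 (2.55-fold lower). Glucocorticoid-induced genes rose (median 0.357, adjusted p = 0.00242, and 0.184 with an estimated correlation), with 2 of 14 genes risen and 0 fallen, or 5 risen and 2 fallen when adjusted over the list alone. Igfbp1, a secreted binding protein for insulin-like growth factors, rose 2.12-fold (log2 change 1.09, SE 0.15, adjusted p = 0.017). Tat, tyrosine aminotransferase, known to be induced by glucocorticoids, rose 2.21-fold (log2 change 1.14, SE 0.14, adjusted p = 0.012). Lymphocyte and antigen presentation markers rose as a list (median 0.287, adjusted p = 0.0165, and 0.309 with an estimated correlation) with 0 of 15 genes called over all probe sets, and 5 higher and 1 lower when adjusted over the list alone. Mitochondrial electron transport genes (median -0.182, 0 of 29 genes called, adjusted p = 0.0384, and 0.218 with an estimated correlation) and proteasome genes (median -0.142, 0 of 26 called, adjusted p = 0.0359, and 0.218 with an estimated correlation) fell as lists. Adjusted over the list alone, 0 genes of either passed. Cyp2b2 fell by 1.17 (SE 0.16), and the cytochrome P450 genes Cyp2c11 and Cyp2a2 rose 2.3-fold and 2.36-fold. Gnmt, a methyltransferase gene of glycine, was 2.0-fold lower, the immediate early gene Junb 2.97-fold lower, and Pik3r1, a subunit gene of phosphoinositide 3-kinase, at least 4.2-fold higher. The lymphocyte list was not called without sham array 1 or either 1 h array (adjusted p up to 0.0739), nor the mitochondrial list without any sham, 1 h or 24 h array (up to 0.161), nor the proteasome list without any of these or 8 h array 1 (up to 0.265). With only the groups compared and with plain designs neither was called (adjusted p of 0.0628 and 0.128, and of 0.0631 and 0.359), nor the mitochondrial list after quantile normalization (0.0585) or the lymphocyte list with no filter (0.0532). With the replicate number as a block the mitochondrial list was not called either (0.0519). Gsta3, Cyp2a2, Cyp2c11 and Junb did not pass without any sham or 1 h array (up to 0.0819, 0.0903, 0.0989 and 0.106), nor Pik3r1 without sham array 2 or 1 h array 2 (up to 0.0512), with the floor at the 10th or 50th percentile (0.188 and 0.349) or with the intensity trend (0.134).

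At 1 h limma called 76 of 5285 probe sets, 42 higher and 34 lower than sham, from 55 named genes, and 51 with the pancreatic enzyme genes left out. Here and below that step left out 12 enzyme genes of the marker list and tested 5271 probe sets. Prss3b, Prss3bl1, Rnase1 and Reg1a were not among the 12, so the 51 are not free of genes known from the pancreas. Calls of other genes, such as Abcc3 and Supt5h, ended as well. The arrays of the groups did not overlap in 2253 of the 5285 probe sets, where chance gives a share of 33.3%. With only the sham and 1 h arrays in the fit limma called 0 probe sets, with 574 at an unadjusted p under 0.05, and the count was 33 without sham array 2, 41 without 1 h array 1 and 29 without 1 h array 2. Without sham array 1 or 1 h array 1, 3 lists were called in place of 6.

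**Figure D1:**
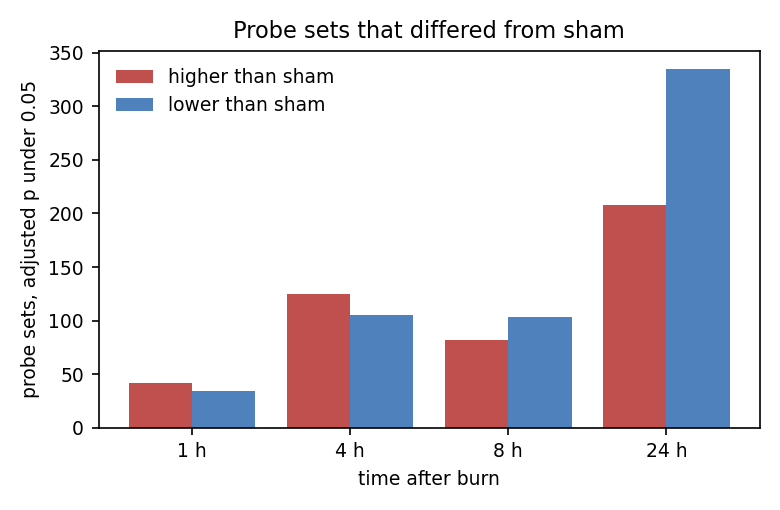
Number of probe sets (vertical axis) called higher or lower than sham at each time after the burn (horizontal axis), from 2 arrays per group. The bars show 42 higher and 34 lower at 1 h, 125 and 105 at 4 h, 82 and 103 at 8 h, and 208 and 335 at 24 h.

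At 4 h, Hmox1, the heme oxygenase that breaks down heme, rose 14.4-fold, from 202 to 2823 (log2 change 3.85, SE 0.24, n = 2 and 2, adjusted p = 0.000311). Alas1, the first enzyme of heme synthesis, rose 7.09-fold (SE 0.29), Pdk4, the kinase that inhibits pyruvate dehydrogenase, 10.8-fold (SE 0.32) and Atp1b1, a subunit of the sodium pump, 11.5-fold (SE 0.17). The interleukin-1 receptor gene Il1r1 rose 7.95-fold on the probe set M95578_at, while U14010_g_at of the same gene had a log2 change of 0.72 with an adjusted p of 0.614. The zinc finger gene Zfp354a rose 6.59-fold, Gtf2ird1 14.1-fold, Slc16a6 6.86-fold and LOC102547700 6.12-fold. Hsd17b2, which inactivates estradiol and testosterone, was 11.6-fold lower (log2 change -3.53, SE 0.18). The mitochondrial carrier gene Slc25a30 was 11.5-fold lower (SE 0.29), Ces2e 18.6-fold (SE 0.42) and Dusp6, a phosphatase gene of MAP kinases, 9.45-fold (SE 0.51). Gpam, the first enzyme of triglyceride synthesis, was at least 9.29-fold lower and Cyp2b3 at least 9.82-fold lower. Gtf2ird1 did not pass without 4 h array 1 (adjusted p = 0.056), nor Slc16a6 without either 4 h array (up to 0.0676). LOC102547700 did not pass without sham array 1 or 4 h array 1 (up to 0.0811) or with the floor at the 50th percentile (0.0575), nor Dusp6 without either sham array or 4 h array 1 (up to 0.0822).

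Of the 12 pancreatic enzyme genes 7 fell at 4 h, and 10 had both 4 h arrays below both sham arrays. Prss1, a trypsinogen, was at least 28.6-fold lower (adjusted p = 4.8e-05), Cpb1 at least 10.5-fold lower and the phospholipase gene Pla2g1b 11.7-fold lower. In the pancreas, muscle and adipose list 8 of 19 genes fell and 0 rose, and 10 fell when adjusted over the list alone (median -0.985, adjusted p = 2.98e-10, and 0.0482 with an estimated correlation). Of the 8, 7 were pancreatic enzyme genes, and the other was the adipose and complement gene Cfd (4.59-fold lower), which did not pass with the floor at the 50th percentile (adjusted p = 0.0668).

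Glucocorticoid-induced genes rose as a list at 4 h (median 0.418, adjusted p = 0.00969, and 0.208 with an estimated correlation): of 14 genes, 5 rose and 1 fell, the same numbers as when adjusted over the list alone. The median was 0.967 without sham array 1 and 0.165 without sham array 2. Igfbp1 rose 2.62-fold (log2 change 1.39, SE 0.15) and the transcription factor gene Klf9 2.09-fold (SE 0.17), while Dusp1, a phosphatase gene known to be induced by glucocorticoids, fell by 1.94 (SE 0.19). Cholesterol synthesis genes fell (median -0.54, adjusted p = 0.000409, and 0.268 with an estimated correlation): 2 of 17 fell and 0 rose, or 8 fell and 1 rose when adjusted over the list alone. Fdft1, squalene synthase, fell by 1.6 (SE 0.16, adjusted p = 0.00198), and Acly, which supplies acetyl-CoA for lipid synthesis, fell by 1.39 (SE 0.16). Of 42 genes of the urea cycle and amino acid catabolism, 7 rose and 1 fell, or 9 and 2 when adjusted over the list alone, and the list was not called (adjusted p = 0.323, with a median of -0.04 beside a mean of 0.15 and a test directed up). Tdo2, which opens the tryptophan ring, rose 3.44-fold (SE 0.16), the aminotransferase genes Got1 and Tat 5.24-fold and 2.4-fold, and the glycolytic gene Aldoa 2.29-fold. The hepatocyte factor gene Foxa2 fell by 2.45 (SE 0.2, adjusted p = 0.000923).

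At 4 h Bmal1, a core clock activator, was at the floor on the sham arrays and rose at least 7.43-fold (adjusted p = 0.000185), Dbp, a clock output gene, was at least 33.4-fold lower (adjusted p = 0.000213), and Nr1d1, a clock repressor that acts on Bmal1, fell by 1.2 (SE 0.17, adjusted p = 0.00932). Of 9 genes in the clock list 1 rose, 2 fell and 6 did not pass, or 1 rose and 4 fell when adjusted over the list alone, and the list was not called (adjusted p = 0.204).

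At 4 h limma called 230 probe sets, 125 higher and 105 lower, from 152 named genes, and 218 with the pancreatic enzyme genes left out. The arrays did not overlap in 2428 of the 5285 probe sets, where chance gives a share of 33.3%. With only the sham and 4 h arrays in the fit the count was 69, and it was 131 and 127 without sham arrays 1 and 2 and 130 and 125 without 4 h arrays 1 and 2. The 3 list calls held with each array left out, where 5 lists were called without 4 h array 2.

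At 8 h, 11 of 26 genes for positive acute phase proteins rose. Lcn2, lipocalin 2, rose 66.2-fold, from 64.8 to 4073 (log2 change 6.05, SE 0.5, n = 2 and 2, adjusted p = 0.00367, and log2 changes of 6.81 and 5.29 without sham arrays 1 and 2), and Orm1, orosomucoid, rose 8.01-fold to 42570 (log2 change 3.0, SE 0.17, adjusted p = 0.000986). Kng2, a T-kininogen gene, rose 3.78-fold (SE 0.16), A2m, alpha-2-macroglobulin, at least 3.54-fold on M22670cds_at, and Serpina3n, a serine protease inhibitor gene, 2.09-fold (SE 0.15). Of the 26 genes 0 fell and 15 did not pass, and 15 rose when adjusted over the list alone (median 0.775, adjusted p = 1.11e-13, and 0.0941 with an estimated correlation). At 4 h 2 of these 26 genes rose and 0 fell, and the list was not called (median 0.039, camera adjusted p = 0.218). Serpina3n lay higher on the 4 h arrays (20338.7 and 24065.6) than on the 8 h arrays (16598.5 and 14902). Among 21 negative acute phase and carrier genes at 8 h 0 rose, 1 fell (Afm, 1.78-fold) and 20 did not pass, or 1 rose and 1 fell when adjusted over the list alone (adjusted p = 0.923, with a test directed up beside a median of -0.053 and a mean of -0.078). Complement genes rose (median 0.386, adjusted p = 0.000439, and 0.122 with an estimated correlation), 3 of 15 over all probe sets and 6 when adjusted over the list alone, with 0 fallen. At 4 h and 24 h that list was not called and lay the other way (medians -0.193 and -0.322, adjusted p = 0.111 and 0.135), with 0 risen and 1 and 2 fallen, the same numbers as when adjusted over the list alone. C4bpa, the binding protein of complement C4, rose 4.2-fold (SE 0.17) and C9, of the membrane attack complex, 2.63-fold. The ferroxidase gene Cp rose 2.09-fold. C9 and Cp did not pass without any sham or 8 h array (adjusted p up to 0.0962 and 0.0991), nor Afm without any of the 10 arrays (up to 0.17), without the 1 h arrays together (0.0831) or with plain designs (0.0612). A2m on M22670cds_at did not pass with the floor at the 50th percentile (adjusted p = 0.742).

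**Figure D2:**
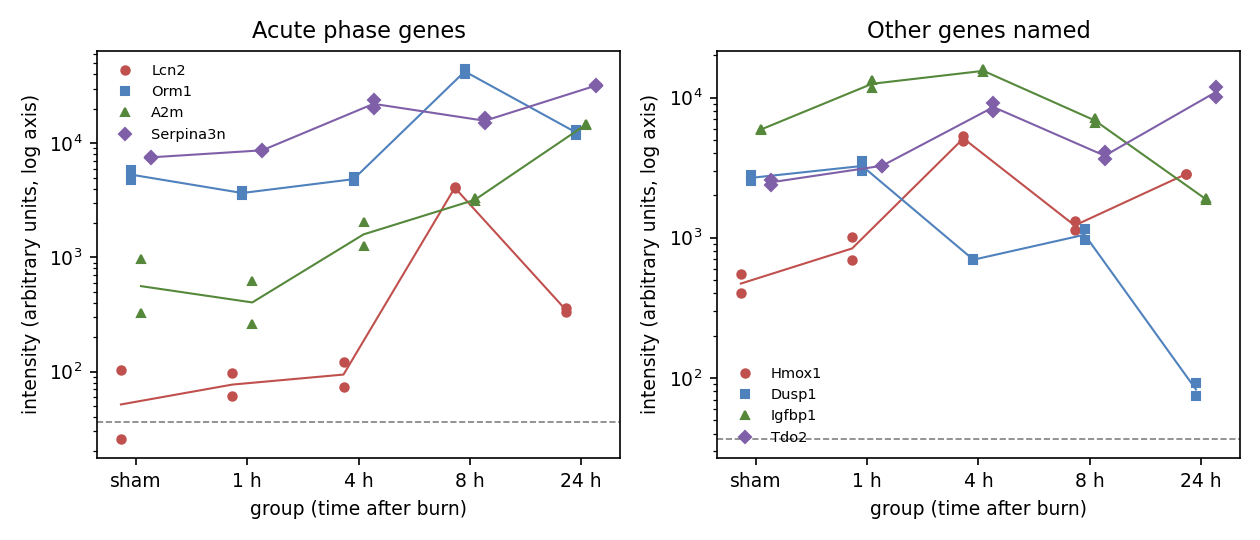
Intensity (log axis, arbitrary units) of 4 acute phase genes on the left and 4 other named genes on the right, by group; points are arrays, lines join the geometric means of the groups and the dashed line is the floor of 36.4. Lcn2 went from a mean of 64.8 in sham to 4073 at 8 h, and A2m, drawn from the probe set used for the lists, lay highest at 24 h.

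Further genes with large increases at 8 h were the imprinted gene H19 (5.95-fold), Akr1c13 of the aldo-keto reductases (5.74-fold, SE 0.23), Erbb2 (3.99-fold) and Cd36 (3.51-fold). A probe set of Pgk1 rose 5.13-fold, while the one used for the lists had a log2 change of 0.53 with an adjusted p of 0.116. Ccnd1, cyclin D1, fell by 2.27 (SE 0.24, adjusted p = 0.00605), the carboxylesterase genes Ces1c and Ces2e were 4.41-fold (SE 0.19) and 22.8-fold lower (SE 0.42), and Dusp6 and Gpam were 6.35-fold and 5.95-fold lower. Without 8 h arrays 1 and 2 the log2 changes were -5.16 and -3.86 for Ces2e, -3.22 and -1.93 for Gpam, and -3.36 and -1.97 for Dusp6. Il1r1 was at least 7.87-fold lower on U14010_g_at, while M95578_at, the probe set that rose at 4 h, had a log2 change of 0.19 with an adjusted p of 0.69. Psat1 was at least 5.08-fold lower, Or1f20 at least 4.87-fold and the sulfotransferase gene Sult1c2a 4.85-fold. Gpam did not pass without any sham or 4 h array (adjusted p up to 0.0986), nor Psat1 without sham array 1 or either 8 h array (up to 0.071). Erbb2 did not pass without any sham, 8 h or 24 h array (up to 0.12), Cd36 without any array but sham array 2 (up to 0.126) and Dusp6 without any array but 8 h array 1 (up to 0.177). Il1r1 did not pass without any sham, 1 h, 4 h or 8 h array (up to 0.159), nor Or1f20 and Sult1c2a without any sham, 1 h, 8 h or 24 h array (up to 0.17 and 0.159). With no filter Erbb2, Cd36, Il1r1, Dusp6, Or1f20 and Sult1c2a did not pass (adjusted p = 0.0505, 0.0553, 0.0802, 0.0809, 0.0665 and 0.0599). With the 1 h arrays left out together Cd36, Il1r1, Dusp6, Or1f20 and Sult1c2a did not (0.071, 0.071, 0.0781, 0.0715 and 0.0692). The floor at the 50th percentile ended the calls of Il1r1, Psat1 and Or1f20 (0.0719, 0.0912 and 0.257). Quantile normalization ended those of Il1r1 and Dusp6 (0.059 and 0.0606), and the intensity trend those of Erbb2 and Cd36 (0.0596 and 0.0509).

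Immediate early genes fell as a list at 8 h (median -0.709, adjusted p = 9.85e-05, and 0.0941 with an estimated correlation): 4 of 23 fell and 0 rose, or 8 when adjusted over the list alone. A probe set of Dusp1 fell by 2.0 (SE 0.24), a call that ended without either sham array (adjusted p up to 0.0659), and Junb fell by 1.32 (SE 0.21). Hepatocyte transcription factors fell as a list (median -0.446, adjusted p = 0.0266, and 0.253 with an estimated correlation) with 0 of 18 genes called, or 4 fallen when adjusted over the list alone. Genes of fatty acid and triglyceride synthesis fell (median -0.319, adjusted p = 0.0475, and 0.226 with an estimated correlation), 2 of 13 or 3 when adjusted over the list alone, with Scd, a desaturase, 3.17-fold lower (SE 0.17) and Lipc, hepatic lipase, 2.45-fold lower. In the clock list (median -0.347, adjusted p = 0.0384, and 0.226 with an estimated correlation) 3 of 9 genes fell and 1 rose, the same numbers as when adjusted over the list alone, and the median was -0.66 without sham array 2 and -0.586 without 8 h array 1. Nr1d1 fell by 1.97 (SE 0.17), Dbp fell by 1.99 (SE 0.28), and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, rose 1.85-fold. Socs2 was 3.21-fold lower (SE 0.26), the kinase gene Jak2 3.92-fold (SE 0.3) and the pyruvate kinase gene Pklr 3.32-fold (SE 0.23). Lipc and Pklr did not pass without either sham array or 8 h array 2 (adjusted p up to 0.0873 and 0.0816), nor Jak2 without any sham or 4 h array (up to 0.106) or after quantile normalization (0.0554). The hepatocyte factor list was not called without either sham array or 8 h array 1 (up to 0.0917), the clock list without any sham, 4 h or 24 h array or 8 h array 2 (up to 0.148) and the fatty acid list without any of the 10 arrays (up to 0.139). With only the groups compared the clock and fatty acid lists were not called (adjusted p = 0.0851 and 0.132), with plain designs the hepatocyte factor and fatty acid lists were not (0.0592 and 0.144), and without the pancreatic enzyme genes the fatty acid list was not (0.0558). The replicate number as a block ended the calls of the clock and fatty acid lists too (0.0653 and 0.0696).

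Mitochondrial electron transport genes (median 0.281, adjusted p = 9.04e-05, and 0.0941 with an estimated correlation) and ribosomal protein genes (median 0.149, adjusted p = 0.000779, and 0.227 with an estimated correlation) rose as lists at 8 h, with 0 of 29 and 0 of 37 genes called over all probe sets and 0 when adjusted over the list alone. After quantile normalization the ribosomal list was not called (adjusted p = 0.123), nor was it without sham array 1 (median 0.085) or 8 h array 1 (up to 0.0627). The median of all probe sets at 8 h was -0.1 as deposited and -0.01 after quantile normalization. In the pancreas, muscle and adipose list 3 of 19 genes rose (Ctrb1, Pnlip and Prss2, at 3.27-fold for Ctrb1 and 2.07-fold for Pnlip on M58369_at), and 3 when adjusted over the list alone (median 0.281, adjusted p = 0.00241, and 0.135 with an estimated correlation). That median was 0.091 without 8 h array 2. Of the 14 glucocorticoid-induced genes 2 rose and 3 fell at 8 h, or 4 and 3 when adjusted over the list alone, and the list was not called (adjusted p = 0.0538).

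At 8 h limma called 185 probe sets, 82 higher and 103 lower, from 132 named genes, and 181 with the pancreatic enzyme genes left out. The arrays did not overlap in 2546 of the 5285 probe sets, where chance gives a share of 33.3%. With only the sham and 8 h arrays in the fit limma called 0 probe sets, with 779 at an unadjusted p under 0.05, and 91 without the 1 h arrays. The count was 48 and 47 without sham arrays 1 and 2, 91 without either 1 h array, 81 without either 4 h array, 78 and 43 without 8 h arrays 1 and 2 and 107 without either 24 h array. Without sham array 1, 5 lists were called in place of 9.

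At 24 h, the drug-metabolising gene Cyp2b2 rose 9.09-fold, from 3214 to 29090 (log2 change 3.18, SE 0.16, n = 2 and 2, adjusted p = 0.000154), and Hmox1 rose 8.23-fold (log2 change 3.04, SE 0.24). A2m rose 26.1-fold on M23566exon_s_at, which had a log2 change of 2.51 and an adjusted p of 0.068 at 8 h (log2 change 4.7, SE 0.58, adjusted p = 0.00407, and log2 changes of 3.91 and 5.5 without sham arrays 1 and 2). Serpina3n rose 4.26-fold (SE 0.15), Orm1 2.34-fold, Kng2 1.99-fold and Lcn2 5.61-fold (log2 changes of 3.25 and 1.73 without sham arrays 1 and 2). Further increases were those of LOC102547700 (12.6-fold), Fam111a (at least 10.1-fold), Ppil3 (9.17-fold), Tuba4a, a tubulin gene (5.09-fold), the retinol dehydrogenase gene Rdh16 (4.92-fold) and Tnfrsf21 (4.53-fold). A probe set of Ugt2b fell by 6.01 (SE 0.61, 64.2-fold, adjusted p = 0.00184) and another fell by 1.77 (SE 0.16). Dusp1 fell by 5.02 (SE 0.19, adjusted p = 3.09e-05), from 2673 to 83.05. Nr0b2 was at least 18.9-fold lower, the electron transfer gene Etfdh at least 14.9-fold and Ces2e 12.7-fold. Lcn2 did not pass without sham array 2 or either 24 h array (adjusted p up to 0.111) or with no filter (0.0572).

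Positive acute phase genes rose as a list at 24 h (median 0.404, adjusted p = 0.000642, and 0.226 with an estimated correlation), with 8 of 26 risen and 1 fallen, or 11 and 2 when adjusted over the list alone, and a median of 0.268 without 24 h array 2. Ribosomal protein genes rose (median 0.393, adjusted p = 3.05e-08, and 0.135 with an estimated correlation), 4 of 37 or 8 when adjusted over the list alone, with 0 fallen. Rpl4 was 1.77-fold and Rps16 1.55-fold higher. Heat shock genes rose (median 0.304, adjusted p = 0.0182, and 0.25 with an estimated correlation), 2 of 13 or 3 when adjusted over the list alone. Hsph1, a chaperone partner, rose 3.55-fold (SE 0.16) and the chaperonin gene Hspe1 2.17-fold. Of 16 genes of endoplasmic reticulum stress and folding 2 rose and 1 fell, or 3 and 2 when adjusted over the list alone, and the list was not called (adjusted p = 0.404). Hspa5, the main chaperone of that compartment, rose 2.61-fold. Mitochondrial electron transport genes (median 0.127, adjusted p = 0.0165, and 0.195 with an estimated correlation) rose as a list with 0 of 29 called, and 0 when adjusted over the list alone. The proteasome list rose (median 0.268, adjusted p = 0.0119, and 0.184 with an estimated correlation), with 1 gene risen (Psmc4, 1.78-fold) and 1 fallen (Psmb8, of the immunoproteasome, 2.28-fold), or 6 and 3 when adjusted over the list alone. The heat shock list was not called without 24 h array 1 (median 0.19, adjusted p = 0.144) and had a median of 0.514 without 24 h array 2, nor the mitochondrial and proteasome lists without sham array 1 or 24 h array 1 (up to 0.0701 and 0.0772). The mitochondrial list was not called with plain designs (adjusted p = 0.118). Hspa5 did not pass without sham array 2 or 24 h array 1 (up to 0.0534), nor Hspe1 without sham array 2 or either 24 h array (up to 0.0945). Rpl4, Psmc4 and Psmb8 did not pass without any sham or 24 h array (up to 0.112, 0.0844 and 0.114), nor Rps16 without any of the 10 arrays (up to 0.151) or without the 1 h arrays together (0.062).

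Bile acid genes fell at 24 h (median -0.667, adjusted p = 6.07e-06, and 0.0941 with an estimated correlation): 6 of 17 fell and 0 rose, or 11 when adjusted over the list alone. Cyp7a1 fell by 2.89 (SE 0.18, 7.42-fold, adjusted p = 0.000291), and Amacr, a racemase of bile acid synthesis, fell by 1.26 (SE 0.18). Cholesterol synthesis genes fell (median -0.679, adjusted p = 4.73e-05, and 0.226 with an estimated correlation), 6 of 17 or 7 when adjusted over the list alone. Fdft1 was 2.82-fold lower (SE 0.16), Insig1, which holds back sterol synthesis, 2.56-fold, and the sterol synthesis genes Nsdhl and Cyp51 2.05-fold and 1.74-fold. Fatty acid and triglyceride synthesis genes fell (median -0.544, adjusted p = 0.0165, and 0.208 with an estimated correlation), 2 of 13 or 3 when adjusted over the list alone, with Acly 2.28-fold lower. Hepatocyte transcription factors fell (median -0.601, adjusted p = 0.00413, and 0.208 with an estimated correlation): 5 of 18 fell and 1 rose, the same numbers as when adjusted over the list alone. Cebpa fell by 1.96 (SE 0.16, adjusted p = 0.000772) and Foxa2 fell by 1.79 (SE 0.2), while Foxa3 rose 3.37-fold (SE 0.23). Insig1 did not pass without either sham array or 24 h array 2 (adjusted p up to 0.0588), nor Nsdhl without sham array 2 or 24 h array 2 (up to 0.0556). Cyp51 did not pass without any sham or 24 h array (up to 0.119), and the fatty acid list was not called without sham array 1 or 24 h array 2 (up to 0.0684, and a median of -0.327 without the latter) or with plain designs (0.0818).

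Genes of the insulin, insulin-like growth factor and growth hormone axis fell at 24 h (median -0.427, adjusted p = 0.0165, and 0.203 with an estimated correlation): 5 of 23 fell and 0 rose, or 6 when adjusted over the list alone. Socs2, an inhibitor of growth hormone signalling, fell by 2.86 (SE 0.26) and Igfbp1 fell by 1.65 (SE 0.15). Of 42 genes of the urea cycle and amino acid catabolism 4 rose and 11 fell, or 5 and 16 when adjusted over the list alone (median -0.31, adjusted p = 0.0119, and 0.226 with an estimated correlation). Tdo2 and Got1 rose 4.41-fold and 3.69-fold. Coagulation genes fell (median -0.287, adjusted p = 0.0359, and 0.226 with an estimated correlation), 2 of 14 or 4 when adjusted over the list alone, with the plasminogen gene Plg 2.72-fold lower (SE 0.14). In the clock list (median -0.627, adjusted p = 0.0359, and 0.226 with an estimated correlation) 2 of 9 fell, Cyp7a1 and Nr1d1 (log2 change -1.44, SE 0.17), or 3 when adjusted over the list alone. Pck1, which commits carbon to glucose synthesis, fell by 1.39 (SE 0.15) and Gclm, of glutathione synthesis, fell by 1.42 (SE 0.16). Of the 14 glucocorticoid-induced genes, a list that rose at 1 h and 4 h, 3 rose and 5 fell at 24 h, or 3 and 7 when adjusted over the list alone, and the list was not called (median -0.547, adjusted p = 0.11). The urea cycle list was not called without 24 h array 2 (adjusted p = 0.0723), nor the growth hormone axis list without 24 h array 1 (median -0.214, adjusted p = 0.0513). The clock list was not called without either sham array or 24 h array 2 (up to 0.126, and medians of -0.361 and -0.381 without sham array 2 and 24 h array 2), nor the coagulation list without any sham, 8 h or 24 h array (up to 0.112). Neither was called with only the groups compared (adjusted p = 0.0593 and 0.0694) or with plain designs (0.167 and 0.152), nor the clock list with no filter (0.0867) or with the replicate number as a block (0.0658).

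Of the 12 pancreatic enzyme genes 10 had both 24 h arrays below both sham arrays. Prss1 was at least 28.6-fold lower (adjusted p = 2.4e-05), Cpb1 at least 10.5-fold, Pla2g1b at least 11.9-fold and Ctrb1 9.3-fold. In the pancreas, muscle and adipose list 8 of 19 genes fell, each a pancreatic enzyme gene, 0 rose, and 10 fell when adjusted over the list alone (median -0.925, adjusted p = 2.27e-05, and 0.0941 with an estimated correlation).

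**Figure D3:**
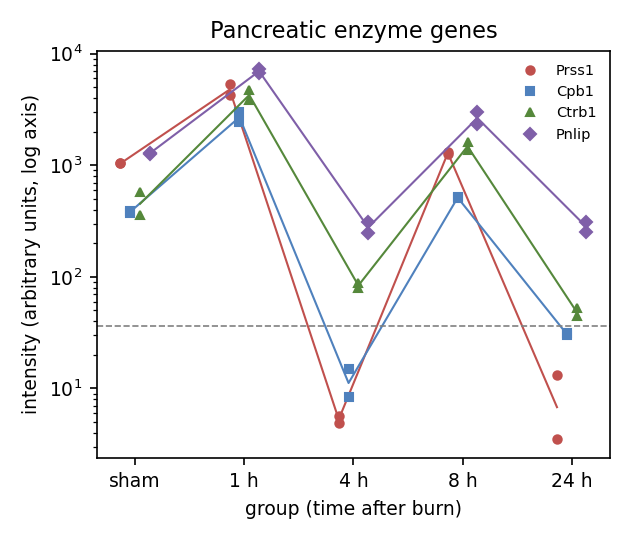
Intensity (log axis, arbitrary units) of 4 pancreatic enzyme genes by group; points are arrays, lines join the geometric means and the dashed line is the floor of 36.4. Both 1 h arrays lay above both sham arrays, and both 4 h and both 24 h arrays lay below them.

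At 24 h limma called 543 probe sets, 208 higher and 335 lower, from 366 named genes, and 531 with the pancreatic enzyme genes left out. The arrays did not overlap in 2844 of the 5285 probe sets, where chance gives a share of 33.3%. With only the sham and 24 h arrays in the fit the count was 104, and it was 263 and 220 without sham arrays 1 and 2 and 244 and 216 without 24 h arrays 1 and 2. The number of lists called was 9 without sham array 1 or 24 h array 1, in place of 14.

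**Figure D4:**
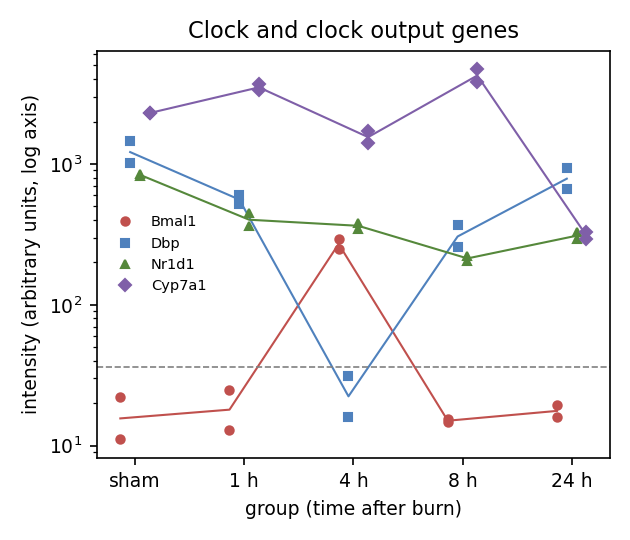
Intensity (log axis, arbitrary units) of the clock genes Bmal1, Dbp and Nr1d1 and of Cyp7a1 by group; points are arrays, lines join the geometric means and the dashed line is the floor of 36.4. Bmal1 lay above the floor on the 4 h arrays, where Dbp lay under it.

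By the F test over the 4 times, 811 probe sets from 539 named genes differed from sham at some time, with 794 without the pancreatic enzyme genes. The count was 492 and 483 without 1 h arrays 1 and 2, and 451 and 446 without 24 h arrays 1 and 2. The mean of the 4 burn groups differed from sham in 156 probe sets, 73 higher and 83 lower, and 154 without the pancreatic enzyme genes. That count was 54 and 31 without sham arrays 1 and 2, 91 and 79 without 1 h arrays 1 and 2, 95 without 4 h array 1 and 88 and 89 without 24 h arrays 1 and 2. With the burn and sham arrays as 2 plain groups limma called 2 probe sets.

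Several genes were called at more than 1 time. Ces2e fell at every burn time, Nr1d1 fell at every burn time, and Hmox1 rose at 4, 8 and 24 h on the probe set used for the lists (10.9-fold, 2.6-fold and 6.04-fold). Of the probe sets called at 4 h and at 24 h, 58 were higher at both, 73 lower at both and 10 opposite, where independent calls would give 4.92 and 6.66. Because both times shared the sham arrays, arrays simulated with no burn effect gave 0.01 shared calls and a correlation of the changes of 0.501, against 0.547 measured. The covariance was 0.2697 against 0.1011 simulated, a difference of 0.1686. The 2 sham arrays could not be split between the times, so part of the excess may come from the shared controls. The 0.01 cannot measure that part, because with no burn effect few probe sets can be called at either time. Between 1 h and 24 h, 9 were higher at both, 18 lower at both and 16 opposite, where independent calls would give 1.65 and 2.16, and the covariance of 0.1011 differed from the simulated 0.1009 by 2e-04.

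The 8 h and 24 h arrays were compared with the 1 h and 4 h arrays to ask which genes differed between late and early times without use of the sham arrays. Myc, a growth-promoting transcription factor gene, was 8.1-fold lower late (log2 change -3.02, SE 0.28, n = 4 and 4, adjusted p = 0.00772), and Wrap73 was 3.87-fold higher (log2 change 1.95, SE 0.16, adjusted p = 0.00541). Each side held 2 times with 2 arrays each, and the fit took the 4 arrays as independent. The p-values of this comparison therefore do not allow for arrays of 1 time being alike. Of the others, the retinoic acid receptor gene Rarb, the phosphatase gene Pdp2, Sephs2 and Zfp354a were 5.46-fold, 7.33-fold, 4.37-fold and 3.88-fold lower, and the phosphate transporter gene Slc34a1, the glycine transporter gene Slc6a9 and the peroxisomal thiolase gene Acaa1b were 2.98-fold, 2.6-fold and 2.53-fold higher. In all 12 probe sets passed, 4 higher and 8 lower, and 4 passed after quantile normalization, 3 higher and 1 lower. The count was 353 in the model of all 10 arrays, 42 without the 1 h arrays, 32 with an intensity trend and robust variance and 26 with the floor at the 50th percentile. The count was 3 and 2 without 1 h arrays 1 and 2, 3 and 2 without 4 h arrays 1 and 2, 6 and 4 without 8 h arrays 1 and 2, and 3 and 2 without 24 h arrays 1 and 2. Myc and Wrap73 passed with each burn array left out, and Wrap73 did not with the floor at the 50th percentile (adjusted p = 0.0948). Slc34a1 passed without 8 h array 2, and Pdp2 and Rarb without 8 h array 1, and did not without any other burn array (adjusted p up to 0.13, 0.144 and 0.101), and Slc6a9, Acaa1b, Sephs2 and Zfp354a did not pass without any of the 8 (up to 0.125, 0.124, 0.102 and 0.125). After quantile normalization Slc34a1, Pdp2, Rarb, Sephs2 and Zfp354a did not pass (adjusted p = 0.0565, 0.0987, 0.0565, 0.0565 and 0.063). They did not pass with no filter either (0.0617, 0.103, 0.059, 0.0717 and 0.0741). The floor at the 50th percentile ended the calls of Slc34a1 and Zfp354a (0.761 and 0.135). With it the log2 changes were 0.08 for Slc34a1, -0.88 for Zfp354a and 0.5 for Wrap73, so these folds depend on the floor. The floor at the 10th ended that of Pdp2 (0.0716), and the intensity trend that of Slc34a1 (0.127). With the 1 h arrays left out together Slc34a1, Slc6a9, Acaa1b and Pdp2 did not pass (0.122, 0.101, 0.078 and 0.115). With the replicate number as a block 2 of the 12 probe sets passed. That setting ended the calls of Slc34a1, Slc6a9, Acaa1b, Pdp2, Sephs2 and Zfp354a (0.079 each) and of Rarb (0.0542).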

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

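The counts over other splits of the arrays were chosen before the result was seen, and the tests on the pancreatic enzyme genes, on the clock genes and on the 4 h and 24 h arrays against the 1 h and 8 h arrays were chosen only after the result was seen.

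The genes below differed between late (8 h and 24 h) and early (1 h and 4 h) burn arrays by the test of that difference. Higher late were Wrap73 (log2 change 1.95, against sham -0.27 early and 1.68 late), Slc34a1 (1.58, from -0.24 to 1.34), Slc6a9 (1.38, from -1.51 to -0.14) and Acaa1b (1.34, from -0.21 to 1.13). Lower late were Myc (-3.02, from 1.4 to -1.62), Pdp2 (-2.87, from 1.49 to -1.38), Rarb (-2.45, from 1.82 to -0.63), Sephs2 (-2.13, from 1.32 to -0.81), Zfp354a (-1.96, from 2.34 to 0.38) and Klf9 (-1.85, from 0.68 to -1.17). Of the 35 splits of the 8 burn arrays into 4 and 4, 2 called as many probe sets as the real one, the real one included, which called 12, and the highest other called 134, so chance cannot be excluded for that count. Splits that part the arrays of a time called 3 at most. Those that keep them together called 12, 134 and 4, too few for a test.

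For burn against sham as 2 plain groups, 15 of the 45 splits of the 10 arrays into 8 and 2, the real one included, called as many probe sets as the real one, which called 2, so chance cannot be excluded. The highest other, the 24 h arrays against the rest, called 174. Setting aside the 1 h, 4 h or 8 h arrays called 13, 47 and 42, so the real split had the lowest count of those that set aside 1 group. Splits that set aside arrays of different groups called 5 at most. For the F test over the 4 times, 1 of 100 pairings drawn for the 10 arrays called as many as the real grouping, the real one itself with 811, and the highest other called 223. Chance can be excluded for which arrays pair, but not for differences between the samples behind the pairs, since arrays made from 1 RNA would give such a count by design.

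The mean log2 intensity of the 12 pancreatic enzyme genes was 8.54 and 8.75 on the sham arrays, 11.13 and 11.13 at 1 h, 6.71 and 6.72 at 4 h, 9.17 and 9.3 at 8 h, and 6.61 and 6.7 at 24 h. The tables argue against scaling between arrays, since the 12 genes changed by 1.55 to 3.75 on the log2 scale at 1 h, where the median of all probe sets was 0.015. At 1 h 9 of these genes were called as deposited and 9 after quantile normalization. That count adds little, because the step could hardly undo changes of this size. Pancreas tissue entering each array's sample on its own cannot be told apart from tissue shared by a group: 1 of 945 pairings, the real one, gave differences within pairs as small (exact p = 0.00106, the smallest those pairings can give), but arrays made from 1 RNA would give this by design, and the labels do not say whether they were. Pancreas tissue in some samples cannot be told apart from a change of expression in the liver after the burn, since either would put 12 of 12 enzyme genes above both sham arrays on both 1 h arrays, where the mean intensity of Pnlip was 6974, of Prss1 4801 and of Ctrb1 4291. The marker list was written before the data were examined and 0 of the other lists hold these genes. How many of them liver itself expresses is not known from these arrays. A change of their expression after the burn stays open and was not tested. The falls at 4 h and 24 h are open in the same way, since pancreas tissue in the sham samples would give them too. Prss1 read 1040.3 and 1038.9 on the sham arrays, 5.7 and 4.9 at 4 h, and 3.5 and 13.2 at 24 h.

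Clock genes differed from sham at each time, with Bmal1, Dbp and Nr1d1 called at 4 h and Nr1d1 at every time. Hour of collection alone, with sham and 24 h arrays taken at one hour of the day, would leave no clock gene called at 24 h, and 2 were called, Nr1d1 and Cyp7a1, the latter also in the bile acid list that fell at 24 h. The labels do not give the hour of collection, so that shared hour is assumed. With only the sham and 24 h arrays in the fit, limma did not call Nr1d1 (adjusted p = 0.0542). Hour of collection alone, for the clock genes not called at 24 h, cannot be told apart from the burn: Bmal1, Dbp and Bhlhe40, 3 genes called at 4 h or 8 h, were not called at 24 h, and Bmal1 lay under the floor on the sham and 24 h arrays. An hour of collection that differed between groups could account for the 3 genes called at 4 h, and it cannot be told apart from the burn because the sham arrays stand for a single time. An effect of the burn on the clock stays open and was not tested.

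The split of the burn arrays into the 4 h and 24 h arrays against the 1 h and 8 h arrays called 134 probe sets, 73 higher and 61 lower at 4 h and 24 h, and it was picked because it called the most of the 35 splits. Splits that keep the arrays of each time together called only 12, 134 and 4. The largest of so few counts, picked for its size, does not by itself show a structure shared by the 4 h and 24 h samples. The tables argue against the pancreatic enzyme genes as the whole source of the count, since they made up 10 of the 134 and 116 were called without them. That count cannot speak against pancreas tissue in some samples. Only 12 enzyme genes were left out, and other transcripts of such tissue would stay among the 116. The tables argue against scaling between arrays as well, since 161 were called after quantile normalization. What the 4 h and 24 h samples may have shared, whether a course of the burn response or the way the samples were taken, stays open and was not tested.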

How the results depend on the processing

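The analyses without the pancreatic enzyme genes and without the 1 h arrays were chosen after seeing the data. Each array left out in turn gave 29 to 75 probe sets at 1 h (76 with all arrays), 125 to 222 at 4 h (230), 43 to 107 at 8 h (185), 216 to 482 at 24 h (543), 446 to 642 by the F test (811), 31 to 129 for the mean of the burn times (156) and 2 to 6 for late against early (12), and 3 to 6, 3 to 5, 5 to 8 and 9 to 14 lists. The floor at the 50th percentile gave 133, 374 and 312 at 1, 4 and 8 h, 272 for the mean of the burn times and 26 for late against early. The intensity trend with robust variance gave 140, 380, 377 and 830 at the 4 times, 1261 by the F test, 317 for the mean, 32 for late against early and 6 lists at 4 h in place of 3. With only the groups compared limma gave 0, 69, 0 and 104 at the 4 times (574, 770, 779 and 1197 at an unadjusted p under 0.05) and 2 for the mean; it could not be run for the F test, and late against early in the model of all 10 arrays gave 353. Plain probe set designs, 3393 of the 5285 tested, gave 34, 126, 67 and 298, 432 by the F test and 91 for the mean, lower in part because fewer were tested. No filter gave 280 at 8 h and 10 lists at 4 h. Quantile normalization gave 4 for late against early. Without the 1 h arrays 91 were called at 8 h and 42 for late against early. The replicate number as a block gave 72, 240, 156, 583, 839 and 149, then 2 for late against early, and 5, 3, 7 and 13 lists. It ended 4 list calls and 13 of the 162 calls of named genes, among them Supt5h at 1 h and Il1r1, Dusp6 and Afm at 8 h. Differences between replicates 1 and 2 correlated at 0.011 to 0.17, over 0.1 in 5 of 10 pairs of groups. Every correlation was positive, so a weak effect shared by arrays of 1 replicate number cannot be excluded. Without the pancreatic enzyme genes the median of the 7 other members of their list was 0.016 at 1 h and -0.023 at 24 h, and the test of the list turned, because its called members had been left out. A fit of 2 plain groups counts differences between the burn times as spread, and the model of 5 groups does not. That spread underlies the 2 for the mean and the 12 for late against early, but not the 156 and the 353. Apart from this and from the enzyme genes left out, the cause of a change in a count or a call was not tested. Of 32 list calls and 162 calls of named genes, 0 reversed in the planned settings, and 16 and 49 held in each of them; only the groups compared ended 102 of the 162. The 162 do not hold every call named here. Those of Igfbp1 and Tat at 1 h and of Nr1d1 and Dbp at 8 h, among others, were not followed through the settings. For such calls the lack of a printed loss does not mean that they held. With only the groups compared, no call of a probe set at 1 h or 8 h held. Of the tested values 2.32% lay at the floor.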

Other observations

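Of 27 cytochrome P450 genes 2 rose and 1 fell at 1 h, 3 rose and 0 fell at 4 h, 2 rose and 1 fell at 8 h, and 5 rose and 2 fell at 24 h, or 3 and 2, 3 and 0, 5 and 3, and 5 and 2 when adjusted over the list alone. Cyp2b2 fell at 1 h (log2 change -1.17) and rose 4.19-fold at 4 h, 3.23-fold at 8 h and 9.09-fold at 24 h. Among 33 genes of fatty acid oxidation 2 rose and 0 fell at 4 h, 1 rose and 1 fell at 8 h, and 2 rose and 3 fell at 24 h, or 3 and 0, 1 and 1, and 3 and 3 when adjusted over the list alone. The enoyl-CoA isomerase gene Eci1 rose 2.42-fold at 8 h and 1.65-fold at 24 h, and the ketone body gene Bdh1 was 4.3-fold lower at 24 h.

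Of 10 macrophage and Kupffer cell markers 1 rose and 2 fell at 24 h, or 1 and 3 when adjusted over the list alone. Clec4f, a Kupffer cell lectin, was 1.76-fold lower and Cyba, a subunit of the phagocyte oxidase, 4.01-fold lower, while Hmox1, which also belongs to the metal handling and antioxidant lists, was 6.04-fold higher. Clec4f did not pass without any sham or 24 h array (adjusted p up to 0.0772), nor Cyba without sham array 2 or either 24 h array (up to 0.091). Of 8 erythroid markers 0 rose and 1 fell at 24 h, over all probe sets and when adjusted over the list alone: the globin gene Hba-a3 was 7.58-fold lower (log2 changes of -3.85 and -2.0 without 24 h arrays 1 and 2), a call that ended without either sham array (adjusted p up to 0.0816).

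In all, 17 of the 36 lists were not called by camera at any time. Their lowest adjusted p was 0.0946 for fatty acid oxidation, 0.101 for macrophage markers, 0.134 for negative acute phase proteins, 0.135 for gluconeogenesis and for metal handling, and 0.138 for antioxidant genes. It was 0.233 for JAK-STAT genes, 0.262 for cell cycle, cytokine and erythroid genes, 0.275 for glycolysis, and 0.388 for apoptosis and for cytochrome P450 genes. The stellate cell, cholangiocyte, endoplasmic reticulum stress and endothelial lists had 0.389, 0.398, 0.404 and 0.553. The fry test called 8, 15, 17 and 22 lists at 1, 4, 8 and 24 h.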
